A study of Mus musculus with 8 samples.

How the data were processed

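Libraries of mouse stromal vascular fraction cells that had been differentiated into adipocytes were sequenced, 8 in all, 4 after DMSO and 4 after DoxSa, and each library was assigned to its group and replicate number from its title. Per the labels' protocols, total RNA was extracted with TRIzol and libraries were made with a VAHTS Universal V6 kit. Whether the reads keep strand is not said there. Per the submitters' processing notes, HISAT2, HTSeq and the mouse genome build GRCm39 were used; versions, the gene annotation and the strand setting are not given in the sources used here. The authors deposited 1 table of FPKM, the reads of a gene scaled to its length and to the reads assigned in the library, with a symbol, an Entrez identifier and annotation terms for each of 22962 genes (17060 protein coding and 5902 non-coding). All 8 columns of values belonged to the 8 samples. FPKM has no correction for a few genes that take much of a library, so a rise of abundant genes lowers the values of all others. No coordinates are given, because the table carries none and the annotation at hand is of another build.

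Because FPKM values of whole reads step by the worth of 1 read, the library total and the length used for each gene could be recovered from the low values. The recovered totals were whole numbers between 39213008 and 41365861 reads. For 12060 of 12060 tested genes the values of all 8 libraries came out as whole reads (within 0.001 of a whole number). On simulated tables made from the real means, lengths and totals, 99.8% of the genes above the FPKM minimum had their true reads recovered in every library.

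The main test was limma (version 3.58.1 in R 4.3.3) on log2(FPKM + 1), with lmFit and eBayes with an intensity trend, on the 12060 genes with a mean of at least 0.5 FPKM over the 8 libraries, with no further scaling and no covariate. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes. SE is the moderated standard error, intervals are 95% intervals of the moderated fit, adjusted p is the Benjamini-Hochberg value over all tested genes, and genes at an adjusted p under 0.05 were called. Gene lists, 40 in all, were fixed before the data were examined, and 33 of them had at least 5 tested members. Of their 1045 entries, 993 matched a gene of the table, 17 of them through an older symbol, and 22255 of the 22962 Entrez identifiers were in the RefSeq gene table. Lists were tested with camera of limma at its preset inter-gene correlation of 0.01, two-sided, with Benjamini-Hochberg adjustment over lists, and again with an estimated correlation and with fry. Several genes stand in more than 1 list, such as Gdf15, Ccl2, Acta2 and Slc7a11, so the lists are not independent. Annotation terms with 15 to 300 tested members were tested with camera in the same way. For 13 marker and quality lists, the mean log2(FPKM + 1) and the share of all FPKM per library were compared by an exact two-sided permutation test over the 70 assignments, with Benjamini-Hochberg adjustment over the 13. Other steps used Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

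The genes named in the text followed a rule fixed before the data were examined, and exceptions are stated beside them. The rule took the 10 largest rises and 10 largest falls among called protein coding genes with non-overlapping groups, a mean of at least 1 FPKM and a symbol that is not a predicted-gene name. It also took, from each list with a list call or at least 3 called members, up to 4 called members in the main direction and up to 2 in the other, by adjusted p. A fixed panel of inflammatory, adipocyte, sphingolipid and stress genes was named whatever its result, as were genes on which a technical weighing rests. This gave 111 genes from the first parts of the rule, of which 110 were tested. Some genes of the panel are not reported here. Genes with near-identical copies, such as Hspa1a and Hspa1b or members of the Ifit family, can share reads, and overlapping or antisense genes cannot be told apart without strand.

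The tests were checked on simulated data. Reads of all 12060 genes were drawn from the real means and totals with 200 genes changed, and the comparison of DoxSa with DMSO was run on the resulting FPKM. Of genes changed 1.3-fold, 86.6% were called in the true direction, of those changed 1.5-fold 97.0% and of those changed 2-fold 100%, with 10 of 11860 unchanged genes called. Of 200 random lists of unchanged genes, 0% had a camera p under 0.05. Camera sets a list against all other genes, and the changed genes among these widen the spread. A low share was thus built in, and the 0% does not measure how often camera calls a list wrongly. All genes were drawn independently and with 1 shared dispersion (0.00289), and the detection rates hold for that dispersion only. The simulation cannot show how often camera calls lists of genes that move together. In the real data the estimated correlation within a list reached 0.76. Alternatives chosen before the data were examined were other pseudocounts (0.1 and 0.25), no filter on low values, a mean of at least 2 FPKM, 3 other scalings, no intensity trend, library quality weights, the replicate number as a block, a threshold of 0.01 and leaving out each library. A voom fit on the recovered reads was added after the data were seen. It called 627 genes higher and 317 lower, and 682 of the 712 genes called in FPKM were among them, all with the same direction.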

Results

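Transcripts of cultured mouse fat cells were profiled by bulk RNA sequencing. The cells came from the stromal vascular fraction of wild-type gonadal fat, the mixture of progenitor, immune and vascular cells that is left when floating adipocytes are removed, and they had been differentiated into adipocytes in culture. They then received either the solvent DMSO or DoxSa on day 6 of the protocol. The labels do not spell DoxSa out, and the series title concerns 1-deoxysphingolipids, atypical sphingolipids that arise when serine palmitoyltransferase uses alanine in place of serine and that lack the hydroxyl group needed for the usual breakdown pathway. The 2 groups held 4 libraries each, numbered 1 to 4. The table gave FPKM for 22962 genes, of which 17060 were protein coding. The recovered library totals lay between 39213008 and 41365861 reads, and 18726 to 19108 genes per library had a value above 0. The labels do not say whether the libraries came from separate cultures or animals, so p-values measure only the spread between these samples.

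The 2 treatments separated along the first principal component, which held 40.4% of the variance of the tested genes. DMSO libraries lay between -9.93 and -4.03 on it and DoxSa libraries between 4.19 and 9.72. The second component held 14.97% and spread the DMSO libraries, with DMSO 1 at 5.81 and DMSO 4 at -8.83. Pearson correlations of log2(FPKM + 1) across genes ranged from 0.9967 to 0.9980 within groups and from 0.9937 to 0.9969 between groups. No pair of libraries of a group agreed within sampling noise, with a chi-square per degree of freedom of at least 5.67.

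**Figure D1:**
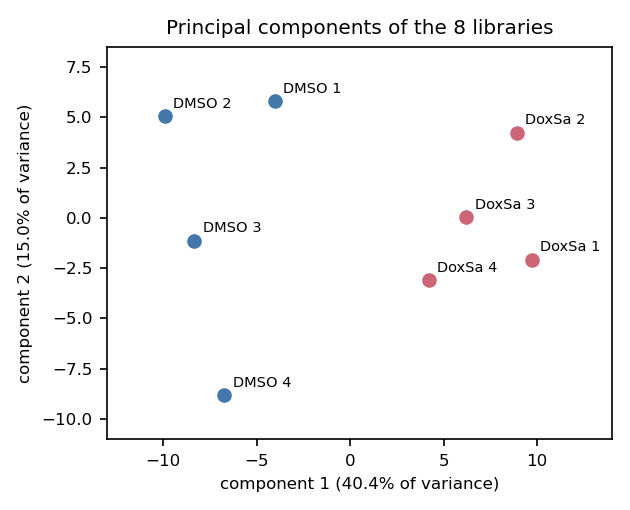
Position of each of the 8 libraries on the first and second principal components of log2(FPKM + 1), with the share of variance on each axis; points are single libraries coloured by group. All 4 DMSO libraries lie below 0 and all 4 DoxSa libraries above 0 on component 1.

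The comparison of DoxSa with DMSO asked which transcripts of differentiated adipocyte cultures change on exposure to the compound. In DoxSa, 18 of 34 cytokine and chemokine genes, 24 of 39 interferon-induced genes, 15 of 30 NF-kB genes, 16 of 37 genes of the integrated stress response and 12 of 28 of the unfolded protein response rose. Of 30 genes of the actin cytoskeleton 17 fell and 1 rose, and of 49 extracellular matrix genes 15 fell and 4 rose. These lists were called by camera at its preset correlation and none with an estimated correlation, where their adjusted p lay between 0.115 and 0.188. Fry, which asks only whether a list moves on balance one way, called each of them (adjusted p between 0.00139 and 0.0376). It did not call the adipocyte identity, fatty acid synthesis or macrophage lists (adjusted p = 0.0579, 0.0526 and 0.0985). In mean level per library the groups overlapped for the interferon list, with DMSO 1 above DoxSa 4. The count of interferon genes called higher was 5 without DoxSa 2 and 0 with no filter on low values. Of 32 adipocyte identity genes 2 fell, with Adipoq at 774 and 772 FPKM in DMSO and DoxSa. Most changes were small, with a median absolute log2 fold change of 0.29 among called genes. Of 12060 genes tested with limma, 468 were higher and 244 lower at a Benjamini-Hochberg adjusted p under 0.05 (n = 4 per group, on log2(FPKM + 1)). At least 1.5-fold changes on this scale, which understates the change of low genes, were found for 61 of the higher and 16 of the lower genes. The groups did not overlap for 1509 genes, or 12.5% of those tested, where chance gives 2.86%, and 667 of the 712 called genes were among them. Quantile normalization gave 384 higher and 316 lower genes in place of 468 and 244, which moved the share called higher from 65.7% to 54.9%. With no filter on low values, 158 genes were higher and 108 lower. The number of calls also depended on single libraries: 247 higher and 154 lower genes were called without DoxSa 1, 233 and 152 without DoxSa 2, 308 higher without DoxSa 3 and 158 lower without DMSO 2.

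The 10 largest rises under the naming rule were those of Cxcl10, Ptgs2, Ifit1, Grem1, Oasl1, Serpinb2, Rsad2, Usp18, Rgs1 and Cxcl2. Ptgs2, which encodes the prostaglandin-forming enzyme cyclooxygenase 2, measured 1.60 ± 0.186 FPKM in DMSO and 6.01 ± 0.942 FPKM in DoxSa (SD, n = 4), a log2 fold change of 1.42 ± 0.09 (SE, adjusted p = 1.97e-05). Grem1, which encodes a secreted antagonist of bone morphogenetic proteins, measured 0.810 ± 0.196 FPKM in DMSO and 3.44 ± 0.271 FPKM in DoxSa, a log2 fold change of 1.2995 ± 0.08 (adjusted p = 1.54e-05). Serpinb2 encodes an inhibitor of plasminogen activators and Rgs1 a regulator of G protein signalling. Their log2 fold changes were 1.19 ± 0.11 and 1.13 ± 0.15. The 10 largest falls were those of Cnn1, Lgr5, Igfbp2, Cemip, Timp3, Ccn3, Actg2, Galnt18, Myl9 and Lurap1l. Cemip, which encodes a hyaluronan-degrading protein, measured 59.96 ± 3.22 FPKM in DMSO and 30.4 ± 4.01 FPKM in DoxSa, a log2 fold change of -0.97 ± 0.08 (adjusted p = 9.53e-05). Igfbp2, which encodes an insulin-like growth factor binding protein, measured 8.62 ± 0.935 FPKM in DMSO and 3.85 ± 1.16 FPKM in DoxSa, with a log2 fold change of -1.02 ± 0.15. The log2 fold changes of Lgr5, Ccn3, Galnt18 and Lurap1l were -1.04, -0.91, -0.73 and -0.66, and Ccn3 lost its call with no filter on low values.

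**Figure D2:**
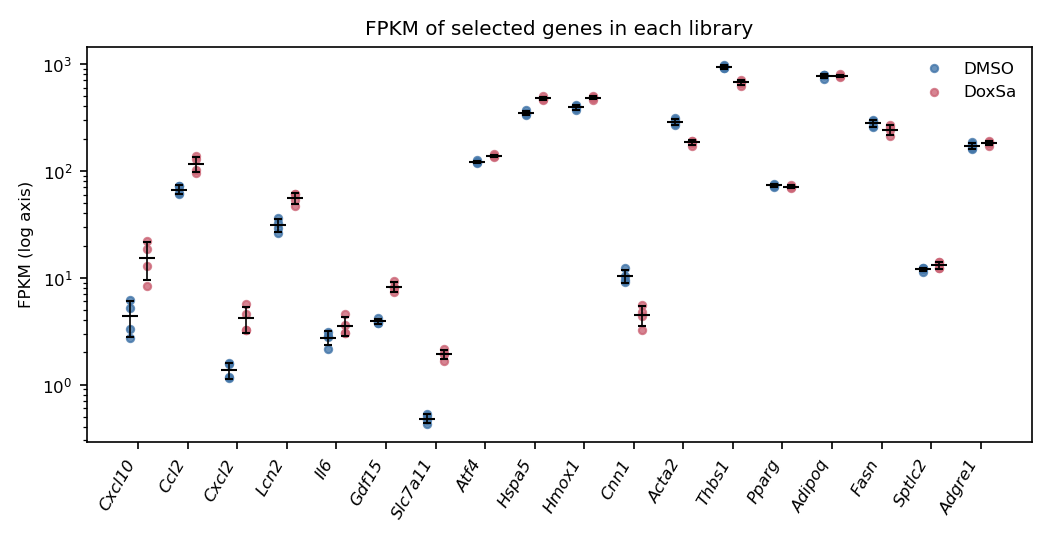
FPKM on a log axis of 18 named genes in each of the 8 libraries; points are libraries coloured by group, and black marks give the mean ± SD of 4 libraries. Cxcl10, Slc7a11 and Gdf15 are higher in DoxSa, the contractile genes Cnn1 and Acta2 are lower, and Pparg and Adipoq overlap between the groups.

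Of 34 tested cytokine and chemokine genes, 18 rose and 0 fell (23 higher and 1 lower adjusted over the list alone). Their median log2 fold change was 0.35 (camera adjusted p = 1.79e-11, and adjusted p = 0.117 with an estimated correlation). Ccl2, the main attractant of monocytes, measured 66.7 ± 6.22 FPKM in DMSO and 116 ± 19.7 FPKM in DoxSa (SD, n = 4), a log2 fold change of 0.78 ± 0.11 (SE, adjusted p = 0.00170). Cxcl10, a chemokine induced by interferons, measured 4.39 ± 1.62 FPKM in DMSO and 15.4 ± 5.93 FPKM in DoxSa, a log2 fold change of 1.58 ± 0.26 (adjusted p = 0.00656). Cxcl2, a neutrophil attractant, measured 1.36 ± 0.229 FPKM in DMSO and 4.17 ± 1.14 FPKM in DoxSa, a log2 fold change of 1.11 ± 0.13 (adjusted p = 7.85e-04). Lcn2, which encodes an iron-scavenging acute phase protein, rose with a log2 fold change of 0.82 ± 0.10, Saa3, a serum amyloid A gene, with 0.69 ± 0.17 and the cytokine gene Lif with 0.51 ± 0.08. Several well known inflammatory genes did not pass the test. The log2 fold change was 0.28 ± 0.11 for Il6 (adjusted p = 0.167), 0.36 ± 0.12 for Tnf (adjusted p = 0.131), 0.16 ± 0.07 for Il1b (adjusted p = 0.269) and 0.56 ± 0.17 for Cxcl1 (adjusted p = 0.0907). Cxcl1 passed it without DMSO 2 or DoxSa 3. Il6 and Il1b were low, at 2.74 and 3.56 FPKM and 1.08 and 1.31 FPKM in DMSO and DoxSa. The number of cytokine and chemokine genes called higher was 11 without DMSO 2, without DMSO 3 or without DoxSa 1, and 9 without DoxSa 2. Saa3 was not called without any 1 of DMSO 2, DMSO 3, DMSO 4, DoxSa 1, DoxSa 2 and DoxSa 3, nor with library quality weights. In addition 1 member was called lower without DMSO 4 and with quantile normalization. With no filter on low values 7 cytokine and chemokine genes were called, and Cxcl10 and Saa3 were not.

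Of 30 tested genes of the NF-kB pathway and its targets, 15 rose and 0 fell (21 higher and 0 lower adjusted over the list alone). Their median log2 fold change was 0.17 (camera adjusted p = 4.50e-13, and adjusted p = 0.115 with an estimated correlation). Besides Ptgs2, the members with the smallest adjusted p were Nfkbie and Nfkbib, which encode inhibitors of NF-kB, and Birc3, an inhibitor of apoptosis. Nfkbie rose with a log2 fold change of 0.37 ± 0.04 (SE, adjusted p = 8.82e-04), Birc3 with 0.29 ± 0.05 and Nfkbib with 0.24 ± 0.04. Without DoxSa 2, 9 members were called, and 5 with no filter on low values.

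The type I interferon list had the largest median log2 fold change of the fixed lists, 0.54 over 39 tested genes, of which 24 rose and 0 fell (36 higher and 0 lower adjusted over the list alone). Its list test gave camera adjusted p = 4.98e-19, and adjusted p = 0.188 with an estimated correlation. Ifit1, an antiviral effector, measured 13.8 ± 5.92 FPKM in DMSO and 37.4 ± 9.86 FPKM in DoxSa (SD, n = 4), a log2 fold change of 1.42 ± 0.26 (SE, adjusted p = 0.0109). Oasl1, an oligoadenylate synthetase-like gene, rose with 1.20 ± 0.20, Rsad2, the gene of the antiviral protein viperin, with 1.19 ± 0.24 and Usp18, a brake on interferon signalling, with 1.13 ± 0.23. Rsad2 lost its call without DoxSa 1 or DoxSa 2 and Usp18 without DoxSa 2. Parp14 and Gbp7 rose with 0.60 ± 0.10 and 0.55 ± 0.09. The libraries of each group differed for this list. Relative to the mean of the 8 libraries, its mean log2 level was 0.04, -0.55, -0.56 and -0.14 in DMSO 1 to 4 and 0.39, 0.43, 0.39 and -0.01 in DoxSa 1 to 4. DMSO 1 thus lay above DoxSa 4. An exact two-sided permutation test of this mean level gave p = 0.0571 (n = 4 per group, adjusted p = 0.0943 over 33 lists). For the cytokine, NF-kB and actin lists, whose groups were apart, the exact two-sided permutation test gave p = 0.0286 (adjusted p = 0.0629). That p is the smallest the design allows, and none of the 33 lists passed an adjusted p of 0.05 in this test. The number of interferon genes called higher was 10 without DMSO 2, 10 without DMSO 3, 6 without DoxSa 1, 5 without DoxSa 2 and 9 without DoxSa 3, and 0 when no filter on low values was applied. It reached 34 when another library was left out, 33 by voom and 27 with a minimum mean of 2 FPKM. The list median lay between 0.464 and 0.636 over left-out libraries.

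**Figure D3:**
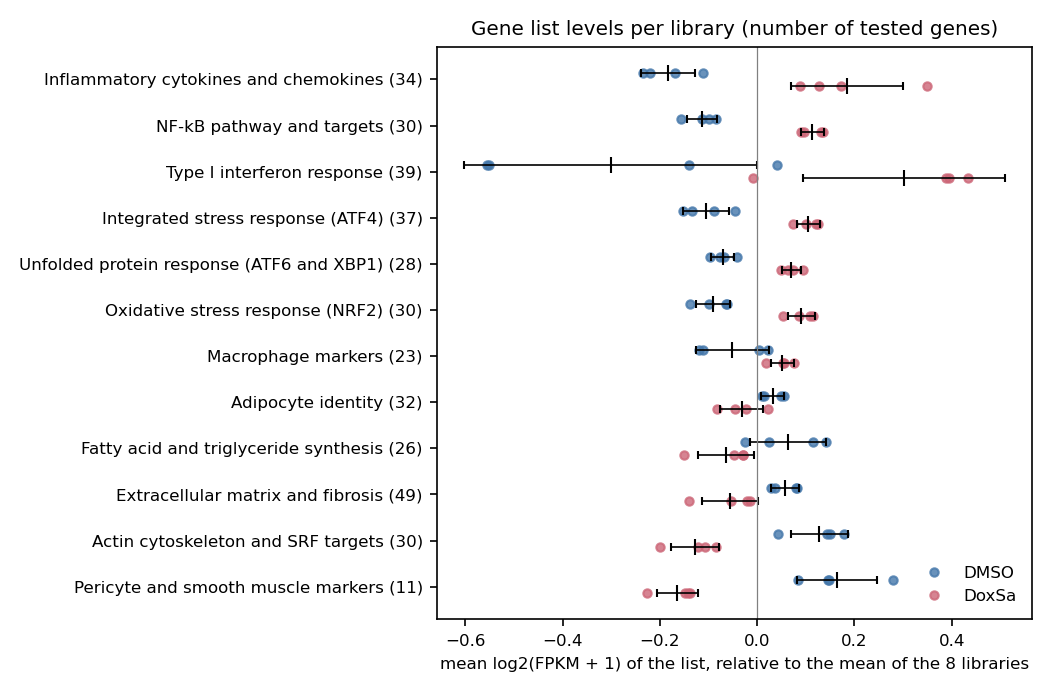
Mean log2(FPKM + 1) of the tested genes of 12 fixed lists in each library, relative to the mean of the 8 libraries; points are libraries coloured by group, and black marks give the mean ± SD of 4 libraries. The groups are apart for the cytokine, NF-kB, stress response, fatty acid synthesis, matrix, actin and pericyte lists and overlap for the interferon, macrophage and adipocyte identity lists. For fatty acid synthesis they are barely apart, with DMSO 1 at -0.0248 and DoxSa 1 at -0.0291.

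Of 37 tested genes of the integrated stress response, the program run by the transcription factor ATF4, 16 rose and 0 fell (23 higher and 1 lower adjusted over the list alone). The median log2 fold change was 0.14 (camera adjusted p = 3.38e-12, and adjusted p = 0.115 with an estimated correlation). Slc7a11, which encodes the cystine importer, measured 0.481 ± 0.0457 FPKM in DMSO and 1.93 ± 0.195 FPKM in DoxSa (SD, n = 4), a log2 fold change of 0.98 ± 0.06 (SE, adjusted p = 1.54e-05). Gdf15, which encodes a stress-induced secreted factor, measured 3.90 ± 0.216 FPKM in DMSO and 8.24 ± 0.825 FPKM in DoxSa, a log2 fold change of 0.91 ± 0.06 (adjusted p = 2.97e-05). Ddit3, the gene of CHOP, rose with a log2 fold change of 0.39 ± 0.05, Ppp1r15a, which encodes a subunit of the phosphatase that resets the response, with 0.45 ± 0.05 and Atf4 itself with 0.18 ± 0.03. Without DoxSa 2, 10 members were called, and 9 with no filter on low values. Of 28 tested genes of the unfolded protein response, 12 rose and 0 fell (14 higher and 0 lower adjusted over the list alone), with a median of 0.13 (camera adjusted p = 6.95e-10, and adjusted p = 0.115 with an estimated correlation). Hspa5, the gene of the endoplasmic reticulum chaperone BiP, measured 348 ± 16.5 FPKM in DMSO and 475 ± 16.5 FPKM in DoxSa, a log2 fold change of 0.45 ± 0.04 (adjusted p = 2.01e-04). Creld2, Hyou1 and Hsp90b1, also genes of endoplasmic reticulum proteins, rose with 0.43 ± 0.06, 0.30 ± 0.04 and 0.25 ± 0.04.

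Of 30 tested genes of the NRF2 oxidative stress response, 13 rose and 1 fell (14 higher and 3 lower adjusted over the list alone), with a median of 0.12 (camera adjusted p = 9.59e-07, and adjusted p = 0.188 with an estimated correlation). The median was 0.0749 with no filter on low values. Txnrd1, which encodes thioredoxin reductase 1, rose with a log2 fold change of 0.64 ± 0.05 (SE, adjusted p = 9.53e-05), Srxn1, the gene of sulfiredoxin, with 0.58 ± 0.06 and Sqstm1, the gene of the autophagy receptor p62, with 0.51 ± 0.04. Hmox1, the gene of heme oxygenase 1, measured 394 ± 20.7 FPKM in DMSO and 484 ± 17.01 FPKM in DoxSa, a log2 fold change of 0.30 ± 0.04 (adjusted p = 0.00294). Nqo1 did not pass the test, at 0.32 ± 0.09 (adjusted p = 0.0679), but passed it without DMSO 2 and by voom. The member that fell was Me1, which is also a lipogenic gene (-0.18 ± 0.05, adjusted p = 0.0492), and it was not called without any 1 of DMSO 2, DMSO 3, DMSO 4 and the 4 DoxSa libraries, nor with no filter, no intensity trend, library quality weights or median-of-ratios scaling. Of 17 tested heat shock genes, 4 rose and 0 fell (10 higher and 1 lower adjusted over the list alone), with a median of 0.13 (camera adjusted p = 4.76e-05, and adjusted p = 0.188 with an estimated correlation). Hspa1a rose with 0.75 ± 0.07 and Hspa1b with 0.46 ± 0.06, but these near-identical copies can share reads, which the counting could divide between them. Hsp90aa1 and Hspa8 rose with 0.23 ± 0.05 and 0.15 ± 0.04. Without DMSO 2, DoxSa 1, DoxSa 2 or DoxSa 4, 2 heat shock genes were called and Hsp90aa1 was not among them. Hspa8 was not called without any 1 of the 8 libraries, nor with no intensity trend, library quality weights or quantile normalization. With no filter on low values 2 heat shock genes were called, and Hsp90aa1 and Hspa8 were not.

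Of 37 tested lysosome and autophagy genes, 6 rose and 0 fell (11 higher and 2 lower adjusted over the list alone), with a median of 0.06 (camera adjusted p = 2.02e-04, and adjusted p = 0.188 with an estimated correlation). Besides Sqstm1, Gpnmb, which encodes a glycoprotein of lysosome-rich macrophages, rose with a log2 fold change of 0.46 ± 0.07 (SE, adjusted p = 0.00344), and the cathepsin genes Ctsl and Ctss rose with 0.22 ± 0.04 and 0.24 ± 0.05. With no filter on low values 3 were called, Ctss not among them, and 1 member was called lower without DoxSa 2, with quantile normalization and with rescaling to equal FPKM sums. Of 23 tested senescence and secretory genes, 9 rose and 1 fell (12 higher and 3 lower adjusted over the list alone), with a median of 0.18 (camera adjusted p = 7.48e-04, and adjusted p = 0.154 with an estimated correlation). Beyond Gdf15 and Ccl2, Timp1, which encodes a metalloproteinase inhibitor, measured 594 ± 34.0 FPKM in DMSO and 771 ± 37.3 FPKM in DoxSa (SD, n = 4), a log2 fold change of 0.38 ± 0.05, and Plaur, the gene of the urokinase receptor, rose with 0.42 ± 0.06. Cdkn2b, the gene of the cell cycle inhibitor p15, fell (-0.27 ± 0.05), though not past the threshold without DoxSa 2, and with no filter on low values 5 members were called higher and 0 lower. By voom, without DMSO 4 or without DoxSa 3, 2 members were called lower. Cdkn1a, the gene of p21, differed by -0.01 ± 0.03 (95% interval -0.08 to 0.07). Of 24 tested p53 targets, 3 rose, namely Gdf15, Plk2 (0.61 ± 0.05) and Plk3 (0.37 ± 0.09), and 0 fell (3 higher and 0 lower adjusted over the list alone). The p53 list had a median of -0.01, a mean of 0.07 and no camera call (camera adjusted p = 0.773, and adjusted p = 0.8288 with an estimated correlation), while fry called it higher (adjusted p = 0.0299). The median was 0.00185 with library quality weights, -0.00592 with no filter on low values, -0.0270 with rescaling to equal FPKM sums, -0.0291 with median-of-ratios scaling and -0.0269 with quantile normalization, and -0.00443 without DMSO 1, 0.00270 without DMSO 2, -0.00638 without DMSO 4, 0.0136 without DoxSa 1 and -0.00356 without DoxSa 3. Plk3 lost its call without DMSO 3, DMSO 4, DoxSa 1, DoxSa 2 or DoxSa 3, and with no filter on low values. With quantile normalization 1 p53 target was called lower. Of 40 tested cell cycle genes, 1 rose and 0 fell (0 higher and 0 lower adjusted over the list alone), and the list was not called (camera adjusted p = 0.764, and adjusted p = 0.887 with an estimated correlation). The gene that rose, Cenpe (0.24 ± 0.06), was named after its value was seen. The list had 0 called genes without DMSO 1, DMSO 2, DMSO 4, DoxSa 1, DoxSa 3 or DoxSa 4, with no filter and with each of 3 other scalings. Mki67, the proliferation marker, measured 9.46 and 10.6 FPKM in DMSO and DoxSa (adjusted p = 0.443).

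Of 30 tested genes of the actin cytoskeleton and other targets of serum response factor, 17 fell and 1 rose (1 higher and 20 lower adjusted over the list alone), with a median log2 fold change of -0.23 (camera adjusted p = 1.15e-20, and adjusted p = 0.115 with an estimated correlation). Acta2, the gene of smooth muscle actin, measured 289 ± 19.3 FPKM in DMSO and 184 ± 8.98 FPKM in DoxSa (SD, n = 4), a log2 fold change of -0.64 ± 0.05 (SE, adjusted p = 9.53e-05). Cnn1, the gene of the actin-binding protein calponin, measured 10.3 ± 1.38 FPKM in DMSO and 4.49 ± 0.942 FPKM in DoxSa, a log2 fold change of -1.05 ± 0.12 (adjusted p = 6.47e-04). Myl9, a myosin light chain gene, fell with -0.68 ± 0.06, and Actg2, a smooth muscle actin gene, with -0.86 ± 0.09. Junb, an immediate early gene, was the member that rose (0.31 ± 0.06), though not past the threshold without DoxSa 2 or with no filter on low values. The count of falls lay between 15 and 17 when any 1 library was left out. The markers of pericytes and smooth muscle cells include several of these genes: of 11 tested, 5 fell and 0 rose (1 higher and 5 lower adjusted over the list alone), with a median of -0.13 (camera adjusted p = 8.59e-07, and adjusted p = 0.117 with an estimated correlation). The median was -0.0801 with no filter on low values and -0.380 with a minimum mean of 2 FPKM. Those that fell were Acta2, Actg2, Cnn1, Lmod1 (-0.63 ± 0.07) and Myh11 (-0.38 ± 0.07), the last named after its value was seen, and 1 marker was called higher by voom and with no intensity trend. The share of all FPKM taken by these markers was 0.0845% ± 0.0052 (SD, n = 4) in DMSO and 0.0551% ± 0.0023 in DoxSa, for which a two-sided exact permutation test gave p = 0.0286, the smallest this design allows (adjusted p = 0.124 over 13 measures). Acta2 alone, at 289 FPKM in DMSO and 184 FPKM in DoxSa, made up most of this share and of its fall. The share thus mainly follows a gene of the actin list and does not measure the number of these cells.

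Of 49 tested extracellular matrix genes, 15 fell and 4 rose (4 higher and 15 lower adjusted over the list alone), with a median log2 fold change of -0.07 (camera adjusted p = 8.46e-09, and adjusted p = 0.188 with an estimated correlation). Thbs1, the gene of thrombospondin 1, measured 936 ± 33.0 FPKM in DMSO and 671 ± 32.8 FPKM in DoxSa (SD, n = 4), a log2 fold change of -0.48 ± 0.04 (SE, adjusted p = 1.71e-04). Ccn2, the gene of connective tissue growth factor, measured 157 ± 5.68 FPKM in DMSO and 108 ± 8.74 FPKM in DoxSa, a log2 fold change of -0.53 ± 0.05 (adjusted p = 3.12e-04). Timp3, which encodes a matrix-bound metalloproteinase inhibitor, measured 69.5 ± 6.85 FPKM in DMSO and 35.6 ± 5.06 FPKM in DoxSa, a log2 fold change of -0.95 ± 0.10 (adjusted p = 3.12e-04). Mmp3, the gene of stromelysin 1, and Timp1 rose, with 0.54 ± 0.11 and 0.38 ± 0.05. The count of rises was 2 without DoxSa 1, DoxSa 2 or DoxSa 3, and with no filter on low values 9 fell and 1 rose, Mmp3 not among them. Col1a1, the gene of the main chain of type I collagen, did not pass the test at -0.10 ± 0.06 (adjusted p = 0.368).

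Of 32 tested adipocyte identity genes, 2 fell and 0 rose (0 higher and 2 lower adjusted over the list alone), with a median log2 fold change of -0.06 (camera adjusted p = 8.19e-06, and adjusted p = 0.188 with an estimated correlation). Retn and Rbp4, which encode the secreted proteins resistin and retinol binding protein 4, fell with -0.20 ± 0.04 (SE, adjusted p = 0.0151) and -0.16 ± 0.04 (adjusted p = 0.0413). Rbp4 lost its call without DMSO 1, DMSO 3, DMSO 4, DoxSa 1, DoxSa 2 or DoxSa 4, and with no intensity trend or library quality weights. With no filter on low values 0 of the 32 were called. The list median was -0.0418 without DMSO 2 and -0.0380 without DoxSa 2. Adipoq, the gene of adiponectin, differed by -0.00 ± 0.04 (95% interval -0.09 to 0.08), and Fabp4, which encodes the adipocyte fatty acid binding protein, by 0.03 ± 0.04 (95% interval -0.07 to 0.12). The differences were -0.04 ± 0.03 for Pparg and -0.07 ± 0.04 for Cebpa, the master regulators of adipogenesis, -0.10 ± 0.04 for Plin1, -0.13 ± 0.07 for Lep, -0.15 ± 0.05 for Slc2a4, the insulin-responsive glucose transporter gene, and -0.00 ± 0.07 for Lpl, with adjusted p of at least 0.128. Slc2a4 passed the threshold without DoxSa 1.

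Of 26 tested genes of fatty acid and triglyceride synthesis, 5 fell and 0 rose (0 higher and 8 lower adjusted over the list alone), with a median log2 fold change of -0.12 (camera adjusted p = 3.19e-09, and adjusted p = 0.188 with an estimated correlation). Those that fell were Slc25a1, the mitochondrial citrate carrier gene (-0.17 ± 0.03, SE), Acly, the gene of ATP citrate lyase (-0.20 ± 0.05), Dgat2 of triglyceride assembly (-0.19 ± 0.04), Pcx, the pyruvate carboxylase gene (-0.21 ± 0.05), and Me1. Between 0 and 2 of them were called without DMSO 2, DMSO 3, DMSO 4, DoxSa 1, DoxSa 2 or DoxSa 4, the 0 without DoxSa 2. The count was 0 with no filter on low values, 1 with no intensity trend and 3 with library quality weights, and quantile normalization ended the calls of Acly and Pcx. Fasn and Scd1 did not pass the test, at -0.19 ± 0.07 (adjusted p = 0.163) and -0.11 ± 0.06 (adjusted p = 0.374). Of 14 tested lipolysis genes 0 were called by limma or by voom, with 4 at an unadjusted p under 0.05, and the list had a median of -0.06 (camera adjusted p = 0.00678, and adjusted p = 0.338 with an estimated correlation). Lipe and Pnpla2, the genes of the main triglyceride lipases, differed by -0.11 ± 0.04 and -0.06 ± 0.05. Of 26 tested genes of fatty acid oxidation and PPAR targets, 1 fell, Acaa1b (-0.25 ± 0.07, adjusted p = 0.0488), a call that ended without any 1 of DMSO 2, DMSO 3, DMSO 4, DoxSa 1, DoxSa 2 and DoxSa 3, with no filter, with no intensity trend and with library quality weights. The list had a median of -0.02 (camera adjusted p = 0.0368, and adjusted p = 0.372 with an estimated correlation), a call of camera that ended without DMSO 2, DMSO 4 or DoxSa 2 and with library quality weights. The median was -0.0364 with rescaling to equal FPKM sums, -0.0391 with median-of-ratios scaling, -0.0336 with quantile normalization, -0.0339 without DoxSa 1 and -0.00499 without DoxSa 2. Without DMSO 4, 1 member was called higher, and with median-of-ratios scaling 2 lower. Of 6 tested thermogenic genes 0 were called by limma or by voom, with 3 at an unadjusted p under 0.05, while 1 was called lower without DMSO 1, and the list test gave camera adjusted p = 0.0391, and adjusted p = 0.188 with an estimated correlation. That list lost its call without DMSO 2, DMSO 4, DoxSa 1 or DoxSa 2 with each of 3 other scalings, with library quality weights and with no filter, and Ucp1 lay below the level at which genes were tested.

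Of 44 nuclear genes of oxidative phosphorylation, 0 were called by limma or by voom and 6 had an unadjusted p under 0.05, with a median of -0.04 (camera adjusted p = 2.17e-05, and adjusted p = 0.262 with an estimated correlation). The median was -0.0211 without DMSO 3. With quantile normalization 1 gene was called lower. Of 13 mitochondrially encoded genes 0 were called by limma, 3 by voom and 4 at an unadjusted p under 0.05, with a median of -0.18 (camera adjusted p = 0.00169, and adjusted p = 0.372 with an estimated correlation). These transcripts took 6.52% ± 0.47 (SD, n = 4) of all FPKM in DMSO and 5.96% ± 0.26 in DoxSa. DMSO 3 and DMSO 4 stood 0.31 and 0.47 above the mean of the 8 libraries on the log2 scale. Without DMSO 4 the list test gave an adjusted p of 0.0719, and 3 members were called without DMSO 1, 1 without DMSO 3, 1 without DMSO 4, 1 with quantile normalization and 1 with a minimum mean of 2 FPKM. The list median was -0.115 without DMSO 3 and -0.0990 without DMSO 4.

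Of 43 tested genes of sphingolipid metabolism, 2 rose and 0 fell (1 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.04 and no camera call (camera adjusted p = 0.106, and adjusted p = 0.188 with an estimated correlation), while fry called it higher (adjusted p = 0.00616), and so did camera with no filter on low values (adjusted p = 0.0400). The rises were those of S1pr1, a sphingosine 1-phosphate receptor gene (0.26 ± 0.05, SE, adjusted p = 0.0173), and Psap, which encodes the precursor of the saposins (0.14 ± 0.03, adjusted p = 0.0446), both named after their values were seen. Only 1 gene of the list was called higher without DMSO 2, DMSO 3, DMSO 4, DoxSa 1, DoxSa 3 or DoxSa 4, and 0 higher and 1 lower without DoxSa 2. With each of 3 other scalings or no intensity trend 1 was called, and with no filter 0. The list median was 0.0262 with median-of-ratios scaling and 0.0272 with quantile normalization. The subunit genes of serine palmitoyltransferase, Sptlc1 and Sptlc2, differed by 0.09 ± 0.05 (95% interval -0.03 to 0.21) and 0.12 ± 0.05 (95% interval 0.00 to 0.23). The ceramide synthase gene Cers2 differed by 0.06 ± 0.03, the dihydroceramide desaturase gene Degs1 by 0.05 ± 0.04 and the cytochrome P450 gene Cyp4f13 by 0.04 ± 0.07. Of 26 tested genes of cholesterol synthesis and uptake 0 were called by limma or by voom, with 6 at an unadjusted p under 0.05 and a median of -0.05 (camera adjusted p = 0.00609, and adjusted p = 0.215 with an estimated correlation). The median of the cholesterol list was -0.0771 with quantile normalization. In that list 1 gene was called higher without DMSO 1 and with a minimum mean of 2 FPKM. Of 13 tested LXR targets 0 were called by limma or by voom, with 4 at an unadjusted p under 0.05, and the list was not called (camera adjusted p = 0.773, and adjusted p = 0.8288 with an estimated correlation).

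Macrophage transcripts were abundant in both groups: Lyz2, the gene of the macrophage lysozyme, measured 4631 ± 329.7 FPKM in DMSO and 5051 ± 227 FPKM in DoxSa (SD, n = 4), and the macrophage marker Adgre1 172 ± 11.7 FPKM in DMSO and 183 ± 7.92 FPKM in DoxSa. Of 23 tested macrophage markers, 5 rose and 0 fell (5 higher and 0 lower adjusted over the list alone), with a median log2 fold change of 0.09 (camera adjusted p = 7.48e-04, and adjusted p = 0.372 with an estimated correlation). The rises were those of Ctss, Cd14 (0.36 ± 0.07, SE), Aif1 (0.22 ± 0.05), Ptprc (0.26 ± 0.06) and Fcgr1 (0.33 ± 0.08), the last named after its value was seen. Without DoxSa 1, DoxSa 2 or DoxSa 3, 2 markers were called, and without DMSO 2, 3 markers. Aif1 lost its call in each of these, and Ptprc without any 1 DoxSa library and with median-of-ratios scaling or quantile normalization. With no filter on low values 0 markers were called, and 3 with quantile normalization, where the list median was 0.0523. Adgre1 and Csf1r differed by 0.09 ± 0.05 and 0.00 ± 0.05. Macrophage markers took 2.09% ± 0.099 of all FPKM in DMSO and 2.24% ± 0.065 in DoxSa (exact two-sided permutation p = 0.0857, adjusted p = 0.223). Lyz2 alone made up the larger part of this share, which therefore mainly follows that gene. Of 15 tested markers of adipose progenitors and fibroblasts, 2 fell and 1 rose (1 higher and 4 lower adjusted over the list alone), with a median of -0.04 (camera adjusted p = 0.0207, and adjusted p = 0.306 with an estimated correlation), and the list lost its call without DMSO 1, DoxSa 1 or DoxSa 4. The median was -0.0583 with no filter on low values, -0.0635 with library quality weights, -0.0186 without DMSO 1, -0.0106 without DMSO 3, -0.0800 without DMSO 4, -0.0150 without DoxSa 1, -0.0871 without DoxSa 2 and -0.0206 without DoxSa 4. F3, the tissue factor gene, fell with -0.39 ± 0.05 and Pdgfrb with -0.23 ± 0.04, while Gfpt2 rose with 0.18 ± 0.05 in a call that ended without any 1 library other than DoxSa 1, with no filter, with no intensity trend and with each of 3 other scalings. Of 6 tested endothelial markers 0 were called by limma or by voom and 0 had an unadjusted p under 0.05 (camera adjusted p = 0.865, and adjusted p = 0.887 with an estimated correlation), while 1 was called lower with no filter, when 18 were tested. Markers of mesothelium, lymphocytes, granulocytes and mast cells, gonadal epithelium and germ cells, red cells, Schwann cells and neurons and the sex-linked transcripts each had fewer than 5 tested genes, and 0 of those genes were called by limma or by voom, with 4 at an unadjusted p under 0.05. Of 4 Schwann cell and neuronal markers, 1 was called lower with each of 3 other scalings, with library quality weights and without DMSO 4. No lymphocyte or red cell marker was tested. In the per-library test of 13 marker and quality measures, 0 mean levels and 0 shares passed an adjusted p of 0.05. Lymphocyte markers, all below the tested level, took 1.35e-04% ± 2.8e-05 (SD, n = 4) of FPKM in DMSO and 2.15e-04% ± 3.6e-05 in DoxSa, and Schwann cell and neuronal markers 0.00580% ± 1.5e-04 and 0.00520% ± 2.6e-04. For both shares, as for that of pericytes and smooth muscle cells, the exact two-sided permutation p was 0.0286, the smallest the design allows (adjusted p = 0.124). The smallest adjusted p of a mean level was 0.186.

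Among the other immune lists, 1 of 13 inflammasome genes rose, Casp4 (0.39 ± 0.05, SE, adjusted p = 0.00142), a caspase gene that responds to bacterial lipopolysaccharide inside the cell, and 0 fell (2 higher and 0 lower adjusted over the list alone). The list had a median of 0.07 (camera adjusted p = 0.0137, and adjusted p = 0.271 with an estimated correlation), 2 members were called without DMSO 1 or DMSO 3, with a minimum mean of 2 FPKM, with rescaling to equal FPKM sums and by voom, and Nlrp3 differed by 0.14 ± 0.06 (adjusted p = 0.209). The inflammasome median was 0.138 at a pseudocount of 0.1, 0.117 at a pseudocount of 0.25, 0.158 by voom and 0.0435 without DMSO 4. Of 15 antigen presentation genes 2 rose and 0 fell (2 higher and 0 lower adjusted over the list alone), the immunoproteasome genes Psmb8 (0.31 ± 0.07) and Psmb9 (0.29 ± 0.06), with a median of 0.17 (camera adjusted p = 4.44e-04, and adjusted p = 0.262 with an estimated correlation). Neither was called without DMSO 2, DMSO 3, DoxSa 1, DoxSa 2 or DoxSa 3, and Psmb9 also lost its call without DMSO 4, while 7 genes were called without DMSO 1 and 0 with no filter. Of 17 complement genes 2 rose and 0 fell (3 higher and 0 lower adjusted over the list alone), namely Cd55 (0.33 ± 0.06), which encodes a complement inhibitor, and Cfp (0.31 ± 0.05), the properdin gene, with a median of 0.09 (camera adjusted p = 0.0390, and adjusted p = 0.435 with an estimated correlation). The complement list lost its call without DMSO 2, DMSO 3, DoxSa 2 or DoxSa 3, with a minimum mean of 2 FPKM and with no intensity trend, and Cfp lost its call with no filter. Its median was 0.0523 with quantile normalization and 0.0494 without DMSO 2. In mean level per library the groups overlapped for the inflammasome, antigen presentation and complement lists (exact two-sided permutation p = 0.0571, 0.0571 and 0.114). In each of these, as in the interferon list, DMSO 1 lay above DoxSa 4. Of 28 genes of hypoxia and glycolysis 1 fell, Adm, the adrenomedullin gene (-0.40 ± 0.06), and 0 rose, with a median of -0.03 (camera adjusted p = 0.00585, and adjusted p = 0.435 with an estimated correlation), with 2 genes called lower without DMSO 3 and a list call that ended without DMSO 4 or DoxSa 1 and with library quality weights. The median was -0.0472 with median-of-ratios scaling, -0.0460 with quantile normalization and -0.00451 without DoxSa 1. Of 28 insulin signalling genes 1 fell, Irs3 (-0.33 ± 0.08), and 0 rose, with a median of -0.04 (camera adjusted p = 0.00862, and adjusted p = 0.188 with an estimated correlation). Irs3 lost its call without any 1 library other than DMSO 2 and DoxSa 3, with no filter and with library quality weights, and the list without DMSO 4. The median was -0.0677 with quantile normalization, -0.0276 without DMSO 4 and -0.0294 without DoxSa 2. Of 53 ribosomal protein genes 0 were called by limma or by voom and 4 had an unadjusted p under 0.05, with a median of 0.06 (camera adjusted p = 2.06e-04, and adjusted p = 0.475 with an estimated correlation). That median was 0.0347 with quantile normalization, 0.0350 without DMSO 4 and 0.0406 without DoxSa 2.

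In all, 28 of the 33 tested lists were called by camera with its preset correlation, 14 higher and 14 lower, and 0 with an estimated correlation. The fry test, which asks only whether the genes of a list move on balance one way, gave 15 lists at an adjusted p under 0.05, of which 13 were also called by camera. Annotation terms carried by the deposited table were tested the same way: of 3287 terms, 305 were called higher and 117 lower. Among them, cellular response to interferon-beta had 22 of 44 genes called higher (unadjusted p = 0.0525 with an estimated correlation), chemokine activity 16 of 27 (p = 0.00754 so estimated), and neutrophil chemotaxis 16 of 51 with 1 lower (p = 0.0148). Stress fiber had 17 of 68 genes called lower (p = 0.0240 with an estimated correlation), the Reactome term Smooth Muscle Contraction 8 of 27 (p = 0.0158), and basement membrane 15 of 75 with 1 higher (p = 0.0573). With an estimated correlation, 112 of the 422 called terms had an unadjusted p under 0.05.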

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

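In the 3 patterns weighed here, the tests of macrophage share, of differing interferon states and of exchanged labels, and the count of genes called in other splits, were chosen after the result was seen. The tests of gene length, of pericyte markers and of the lists and terms called in other splits were written down before.

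The number of called genes is larger than other groupings of the libraries give. In 1 of the 35 splits of the 8 libraries into 4 and 4, the real one, as many as 712 genes were called by limma. The highest count of the other splits was 0 (1103 at an unadjusted p under 0.05, against 2393 in the real split, and 30 by voom, against 944). The real split thus stood far apart from the others, at 1 in 35, the smallest share that these splits allow. For the fixed lists the real split also ranked first, with 28 called and at most 24 in another (1 of 35 as large). This narrow margin does not exclude chance by itself. The other splits called a median of 10 lists, so a single list call at the preset correlation carries little weight. For annotation terms chance cannot be excluded: 2 of the 35 splits called at least the 422 terms of the real one, and the highest other count was 444. That split set DMSO 1 with DoxSa 1, DoxSa 2 and DoxSa 4, so it kept part of the treatment difference. Splits with 2 libraries of each group on either side called at most 275 terms and at most 12 lists, with the treatment difference in their spread. None of the other splits is therefore a clean measure of chance.

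The cytokine and chemokine list had a median log2 fold change of 0.35, with 18 of 34 genes called, in cultures rich in macrophage transcripts. A larger share of macrophages in DoxSa would raise the macrophage markers at least as much, because macrophages cannot supply more than all of the chemokine transcripts. The 23 markers, however, had a median of 0.0908 (two-sided permutation of genes between the lists, p = 0.00123). That test takes genes as independent, though estimated correlations were 0.47 among the markers and 0.18 in the cytokine list. Its p is therefore too small and measures no spread between cultures. The abundant Lyz2, Csf1r and Cd68 differed by 0.13 ± 0.06, 0.00 ± 0.05 and 0.12 ± 0.05, while Ctss and Cd14 rose with 0.24 ± 0.05 and 0.36 ± 0.07. Over all tested genes fold change barely followed gene length (Spearman correlation -0.037). Gene length is argued against by that weak trend and by the median of 0.346 that was left when it was removed. Higher chemokine expression per cell in response to DoxSa, in macrophages, adipocytes or progenitors, is a candidate explanation that stays open and was not tested, and bulk values do not show which cells changed.

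The type I interferon list had the largest median, yet DMSO 1 lay above DoxSa 4. An interferon state that varied between cultures whatever their treatment stays possible: 2 of the 35 splits gave a difference in the mean list level at least as large as the real 0.60, and the highest other split gave 0.63. That split exchanges DMSO 1 and DoxSa 4, but exchanged labels are argued against by the 0 genes called by limma over the whole table with these libraries exchanged, against 712 as labelled (30 against 944 by voom, the only other split with a voom call, and 1029 against 2393 at an unadjusted p under 0.05). A larger share of macrophages is argued against by the macrophage markers, whose median lay below that of the interferon list by a difference of -0.453 (two-sided permutation of genes, p = 2e-05, with 39 and 23 genes). Here too the test takes genes as independent, against an estimated correlation of 0.76 in the interferon list. Its p is therefore too small and measures no spread between cultures. An effect of DoxSa on interferon signalling, on top of a state that differs between cultures, remains open and was not tested.

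The actin and serum response factor list had a median log2 fold change of -0.23, with 17 of 30 genes called lower and the groups apart in every library. Gene length is argued against by its weak trend over all tested genes (Spearman correlation -0.037 with fold change) and by the median of -0.238 left after that trend was removed. Whether the DoxSa cultures held a lower share of pericytes or smooth muscle cells cannot be told apart from lower expression per cell: the 7 tested markers of these cells outside the list had a median of -0.0727, which did not differ past the threshold from the list (two-sided permutation of genes, p = 0.297), and 7 genes are too few. Among them Myh11 fell (-0.38 ± 0.07), while Mcam, Notch3 and Cspg4 differed by -0.07 ± 0.07, -0.13 ± 0.06 and 0.11 ± 0.09, and Abcc9 by 0.19 ± 0.06 (adjusted p = 0.0708, and 0.0199 by voom). Smtn and Des differed by -0.05 ± 0.04 and -0.09 ± 0.07. Lower activity of serum response factor in DoxSa is a candidate that was not tested.

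Of 314 groups of 4 values examined (named genes, list levels, marker shares and library totals in each treatment), 20 held 1 library far from the other 3, measured as its gap to the nearest divided by the range, where chance gives about 1 in 20. In DMSO 2 the ratio was 0.926 for Lgr5, at 3.26 FPKM against at most 2.07. It was 0.954 for Actg2 in DMSO 2, at 14.5 FPKM against at most 11.5. Galnt18 in DMSO 2 had 0.906, at 12.3 FPKM against at most 10.1. Lurap1l had 0.839 in DMSO 2, at 18.4 FPKM against at most 16.5, and Lmod1 0.846, at 5.89 FPKM against at most 4.94. The library total of DMSO 2 was the lowest of its group, with 0.848, and its share of gonadal epithelium and germ cell markers the highest, with 0.861, at 5.28e-04% of FPKM. Plk2 was lowest in DMSO 4, with 0.860, at 12.9 FPKM against at least 14.2, and Col1a1 lowest in DMSO 3, with 0.858, at 1209 FPKM against at least 1328. The mean level of the cholesterol synthesis list was lowest in DMSO 1, with 0.945. Among DoxSa libraries, Timp3 was lowest in DoxSa 1, with 0.847, at 28.1 FPKM against at least 37.4, and Gpnmb highest, with 0.8292, at 64.6 FPKM against at most 54.3. The pericyte and smooth muscle list was lowest in DoxSa 1 too, with 0.876. Retn was highest in DoxSa 3, with 0.866, at 342.6 FPKM against at most 335.5, and so was the share of progenitor and fibroblast markers, with 0.921, at 0.509% of FPKM. Mmp3 was lowest in DoxSa 4, with 0.892, at 3.601 FPKM against at least 5.15. The interferon list was lowest in DoxSa 4, with 0.898, and the inflammasome list too, with 0.916. The fatty acid synthesis list was lowest in DoxSa 2, with 0.855. Red cell markers had a value above 0 in DoxSa 4 alone of its group, with 1.00, at 1.24e-05% of FPKM.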

How the results depend on the processing

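The voom fit was added after the data were seen; the other settings were planned. Across settings, 468 higher and 244 lower genes became 158 and 108 with no filter on low values, when all 22962 genes were tested, and 123 and 88 at an adjusted p under 0.01, a stricter threshold on the same test; the cause of the first was not tested. Leaving out 1 library gave 233 to 490 higher and 152 to 235 lower genes, with fewer samples. The other settings gave 384 to 627 higher and 209 to 317 lower, and 0 of the 712 called genes changed sign in a setting that tested them, with 83 not tested at a minimum mean of 2 FPKM and up to 3 when a library was left out. With the replicate number as a block, 415 genes were higher and 209 lower. The values gave little sign that the numbers pair the samples. The deviations of same-numbered libraries from their group means correlated by -0.06, 0.05, -0.10 and 0.07, and only number 2 correlated best with its own number. The labels do not say whether a number marks a shared culture, animal or day, and so few libraries cannot exclude it. In the fit with the block 28 lists were called. The calls of Rbp4, Acly, Pcx, Acaa1b, Me1, Hspa8, Irs3 and Gfpt2 were not made in it and those of Cxcl1 and Nqo1 were, with 2 fatty acid synthesis genes called in place of 5, 1 sphingolipid gene in place of 2 and 1 thermogenic gene in place of 0. Of the 28 lists called by camera, 0 kept the call with an estimated correlation. Fry, which tests another question, called 15 lists, 13 of them among the 28. Camera at its preset correlation called 23 to 27 lists when 1 library was left out. The sphingolipid list was called with no filter (adjusted p = 0.0400) and by fry (adjusted p = 0.00616), and the p53 list by fry (adjusted p = 0.0299). Marker measures past the threshold stayed at 0 in 9 further settings, which the small design largely fixes.

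Uncalled values near 0 changed sign in some settings, and the cause was not tested. The log2 fold change of Adipoq was 0.00465 with quantile normalization and -0.0313 to 0.00939 when 1 library was left out. The log2 fold change of Lpl was 0.0173 with library quality weights and -0.0487 to 0.0587 over left-out libraries. Over left-out libraries, the log2 fold change of Cdkn1a was -0.0250 to 0.0103 and the log2 fold change of Cyp4f13 -0.00269 to 0.0948. The adjusted p of list Cell cycle and proliferation was 0.952 with quantile normalization and 0.223 to 0.934 over left-out libraries. Over the same, the adjusted p of list Endothelial markers was 0.711 to 0.945 and the adjusted p of list LXR targets and cholesterol efflux 0.468 to 0.954. The mean level difference of Mesothelial markers was 0.0613 at a pseudocount of 0.1 and -0.0226 to 0.00343 over left-out libraries. The mean level difference of Gonadal epithelium and germ cell markers was -0.0407 to 0.00134, and the mean level difference of Erythroid markers -0.00624 to 0.00415.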

Other observations

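Some called genes outside the naming rule were also among the larger changes, and were chosen after their values were seen. Spp1, the gene of the secreted matrix protein osteopontin, measured 224 ± 6.09 FPKM in DMSO and 445 ± 61.5 FPKM in DoxSa (SD, n = 4), a log2 fold change of 0.98 ± 0.08 (SE, limma adjusted p = 9.53e-05). Hmga2, which encodes a chromatin protein of proliferating and mesenchymal cells, measured 2.46 ± 0.122 FPKM in DMSO and 4.95 ± 0.305 FPKM in DoxSa, a log2 fold change of 0.78 ± 0.05 (adjusted p = 1.97e-05). Atf3, a stress-induced transcription factor gene, rose with 0.68 ± 0.09 and Mmp12, the macrophage elastase gene, with 0.62 ± 0.15. Col12a1, a fibril-associated collagen gene, measured 139 ± 5.13 FPKM in DMSO and 102 ± 10.4 FPKM in DoxSa, a log2 fold change of -0.45 ± 0.06 (adjusted p = 0.00237).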
